A study of Mus musculus with 2 samples.

How the data were processed

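The series holds 2 libraries from the cerebral cortex of male C57BL/6 mice aged 2 months, made per the labels from pooled cortices of 3 mice. Both start from chromatin that was cross-linked, sonicated and immunoprecipitated with antibody clone 4H8 against RNA polymerase II phosphorylated on serine 5 of its C-terminal repeats (Pol II Ser5P), the form enriched near the start of transcription. In 1 library the immunoprecipitated DNA was sequenced directly (ChIP-seq). In the other it was treated with bisulfite, which converts unmethylated cytosine so that it is read as thymine (ChIP-bisulfite-seq). The protocol text in the labels mentions bisulfite conversion for both samples, and the ChIP-seq library was taken as unconverted from its title and molecule label. Per the labels, 100 ng of immunoprecipitated DNA went into a library and was sheared again to about 150 bp. There was 1 library per assay, so no value has a replicate and no test between conditions was possible. Whether the 2 libraries came from the same chromatin is not given in the sources used here, and no input library was used here.

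For each library the authors deposited a list of read ends with a signal value per position and strand and a read length of 50 bp. Every signal value was a whole multiple of 0.5, which was taken as 1 read end. For the bisulfite library the authors also deposited the percent methylation of each covered cytosine with the count of methylated and the count of unmethylated calls. The percent equalled the value from the counts to within 0.01 in every line. Only cytosines in CpG context appeared to be listed, and non-CpG methylation was not analysed here. The submitters' processing notes name Bismark 0.7.7, Bowtie 0.12.7, HOMER and mm10, without saying which step each served. Positions in the methylation file lay 1 bp below those of the read files, judged from where reads start around called cytosines on chromosome 11, so 1 was added. Coordinates are mm10, counted from 1.

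Gene positions came from a RefSeq gene table of assembly GRCm38.p6, which shares the chromosome coordinates of mm10. The table gives neither strand nor transcripts, and no genome sequence was used here. The planned analysis of annotated transcription start sites was therefore replaced by both ends of each of 21631 protein-coding genes on the 19 autosomes and X, 43262 ends in all. A start site lies at 1 of the 2 ends of a gene and the other end is where it stops, and internal start sites are missed. The planned CpG observed to expected ratio was replaced by CpG calls per read base in the bisulfite library. The cuts of 2.74 and 6.39 CpGs per 100 bp divide the ends with measured methylation into low, middle and high classes of equal size. The most upstream start site and the dependence on GC content were planned and not run, for the same reason. Most other choices followed the plan made before the data were examined. Exceptions are the added settings named in the section on processing and the later choices marked under other observations.

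Each position and strand was counted once, which left 61245087 ChIP-seq and 75068451 bisulfite read ends on the autosomes and X. ChIP-seq reads were moved 75 bp and bisulfite reads 25 bp towards the fragment centre. The bisulfite shift is smaller because both mates were recorded on the same strand, at a spacing of about 80 bp, against 150 bp between opposite strands in ChIP-seq. Reads within 500 bp of an end were compared with the larger of the genome mean and the density 2 to 10 kb away. An end was called when it had at least 4-fold more reads and a Poisson upper-tail test with Benjamini-Hochberg adjustment under 0.001. This test compares positions within 1 library. The same calls in 500 bp windows, joined when adjacent, gave regions.

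Methylation is the share of methylated among all CpG calls within 250 bp of an end, reported for ends with at least 20 calls on at least 3 cytosines. Classes are under 20%, 20 to 80% and over 80%. Intervals are exact 95% Clopper-Pearson intervals over calls, or over ends or genes where a share of these was called. They cover counting error only, since reads without molecular identifiers are not independent molecules. Ends of the same gene or in a shared window are not independent either. Each end was also set against the sequence 1 to 3 kb on both sides with a two-sided Fisher's exact test, Benjamini-Hochberg adjusted under 0.05, with at least 20 calls on each side. For 13 gene lists fixed in advance, the end with more ChIP-seq reads stood for the gene, and all symbols were matched. A list's median was placed as a percentile among 10000 random lists of the same size, matched on CpG class and, for methylation, on reads. Percentiles describe these libraries and are not p-values.

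Genes named in the text followed a rule set before the data were examined. They are the 10 ends with the most reads, the 10 called ends with the highest methylation and at least 50 calls, the 10 ends not called with the lowest methylation, the 5 ends with the smallest Fisher p in each direction, up to 4 members per list by calls with members of a differing class, and the 5 regions away from gene ends with the most reads. Other names are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

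In simulated data with 200 of 43262 ends raised, the calling step recovered 200 at 5-fold and 0 at 3-fold, with 0 false calls. Its counts were drawn from a Poisson distribution around the background that the test uses, so the outcome does not measure errors in real reads. With real reads, 35 positions 100 kb away from the ends were called. In simulated calls at 18590 ends, Fisher's test recovered 164 of 200 ends lowered to 0.2 of the flank level and 130 of 200 lowered to 0.5, with 7 and 10 false calls. These calls were drawn independently of each other, whereas real calls can share a read. The false calls therefore do not measure errors in real data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.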

Results

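The methylation state of DNA bound by Pol II Ser5P in mouse cortex was examined with 1 ChIP-seq and 1 ChIP-bisulfite-seq library. After removal of repeats at the same position, the ChIP-seq library held 61245087 read ends on the autosomes and X and the bisulfite library 75068451, where 4.44% and 1.98% of the original read ends had been repeats. The bisulfite library gave 38144620 CpG calls on 21139847 autosomal cytosines, a mean of 1.8 calls per cytosine. Single cytosines were therefore not compared, and calls were pooled over windows. Across all autosomal calls 58.4% were methylated, and 22.8% of the calls on cytosines with at least 5 calls. No value has a replicate.

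The first comparison asked where Pol II Ser5P was concentrated. Of 43262 gene ends, 853 (1.97%) were called, against 35 at positions 100 kb away. The called ends belonged to 838 genes, and in 823 of them a single end was called. Sirt4 (chromosome 5, position 115490264, gene 75387), a mitochondrial sirtuin, had the most reads, at 19-fold over the genome mean, but the small RNA gene Gm24407 ends 10 bp away. Polg2, a subunit of the mitochondrial DNA polymerase, was at 18.3-fold and the histone gene H2bc18 at 17.9-fold. Polr2a (chromosome 11, position 69758633, gene 20020), the largest subunit of RNA polymerase II itself, was at 17.4-fold. The transcription factor gene Sox2 was at 17.8-fold, with H2-DMa at 17.2-fold and the translation factor gene Eif4a2 at 17.1-fold. Lrrc14 and Lrrc24, whose ends lie 179 bp apart, were at 17.8-fold and 17.5-fold. Of the 10 ends with the most reads, those of Sirt4, H2bc18 and Polr2a were called. The density 2 to 10 kb away kept the others under 4-fold. The count depends on this threshold, since 8244 ends (19.1%) were called at 2-fold, against 842 at positions 100 kb away, and 7385 against the genome mean alone, while 201 were called within 1000 bp and 17 at 8-fold.

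Called ends were almost free of CpG methylation. Over 846 called ends with enough calls, 1.22% of 337592 calls were methylated (1.19 to 1.26%), and 824 of them (97.4%) were under 20%. The 17873 measured ends that were not called had 6.42% (6.39 to 6.45%), with 11968 (67.0%) under 20% and 2272 (12.7%) over 80%. The mean over ends was 2.29% for called and 24.1% for other ends, and the medians were 0.826% and 1.90%. At Polr2a 10 of 1496 calls were methylated (0.668%, 0.321 to 1.23%). Sirt4 had 0.889% of 1463 calls and H2bc18 1.15% of 869 calls. Sox2 and Lrrc14, both not called, were higher, at 5.05% of 218 calls and 8.46% of 130 calls. Enough calls were present at 99.2% of called ends and at 42.1% of the others, so the comparison leaves out most ends with few reads. For called and other ends, the values were 1.17% and 3.15% with at least 50 calls, 1.6% and 10.2% within 500 bp, and 2.27% and 13.0% with calls at 2-fold.

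Low methylation was not limited to called ends. The 10 ends not called with the lowest methylation had no methylated call at all. They include Lcmt2 (0 of 572 calls, upper bound 0.643%), the autophagy gene Gabarap (0 of 558, upper bound 0.659%), Stard7, Ppp1r13b, Natd1, Chtop, Fam53a, Nfx1, the NAD salvage enzyme gene Nampt (0 of 476, upper bound 0.772%) and the phosphatase subunit gene Ppp1cb. Their reads lay between 2.73-fold (Ppp1r13b) and 13.0-fold (Gabarap) over the genome mean. Ends at 2-fold to 4-fold over background had 2.47% methylation over 7021 ends.

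The 22 called ends with 20% methylation or more formed the exception. The gene table gives no strand, so whether such an end is the start of its gene or where the gene stops is not known. Fth1, the ferritin heavy chain gene (chromosome 19, position 9985111, gene 14319), had 62.2% of 148 calls methylated (53.8 to 70.0%) at 4.58-fold over background, in a window it shares with Best1 (60.6% of 132 calls), whose end is 61 bp away. Among the ends of this group with at least 50 calls, the ribosomal protein genes Rps2 (61.3% of 75 calls) and Rps29 (60.4% of 53 calls) followed, with Arl6ip4 at 50.3% of 161 calls. Ends with fewer calls, not ranked here, reached 83.3% of 24 calls. The histone gene H3f3b had 38.1% of 113 calls and the translation factor gene Eif1 37.5% of 120 calls. Mpv17l2 and the synaptic vesicle gene Rab3a share a window 41 bp apart and had 37.4% and 37.0%. Septin3 had 34.3% of 70 calls. At the opposite end of Eif1, also called, 0.558% of 1434 calls were methylated. In 16 of the 18 genes of this group with a measured opposite end, that end was under 20%.

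The ends of 1 gene were compared in the 226 genes with 1 called end and both ends measured. The called end had 1.77% methylation (1.69 to 1.86%) and the other end 19.9% (19.3 to 20.4%), with medians of 0.857% and 65.4%. The called end was lower in 187 genes, higher in 38 and equal in 1. It was lower by at least 20 percentage points in 164 genes and higher by as much in 15.

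Methylation was lowest next to the end in each group of the profile by distance. In genes over 6 kb, methylation at 716 called ends was 0.928% (0.858 to 1.00%) in the first 100 bp inside the gene, where ChIP-seq reads reached 8.31-fold over the genome mean. It stayed under 20% from 900 bp outside to 1200 bp inside the gene, and was 71.9% at 3 kb outside and 72.2% at 3 kb inside. The other ends of the same genes had 36.4% in the first 100 bp inside, with reads at 2.08-fold. Ends of genes without a called end had 6.33%, with reads at 2.45-fold. As a mean over cytosines with at least 5 calls, these values were 19.9% and 2.95%, and the value 3 kb outside called ends was 43.6% over 26 cytosines. Genes without a called end enter with both ends, whereas the other ends of called genes leave out the called one. These groups therefore differ in kind and cannot be set against each other.

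**Figure D1:**
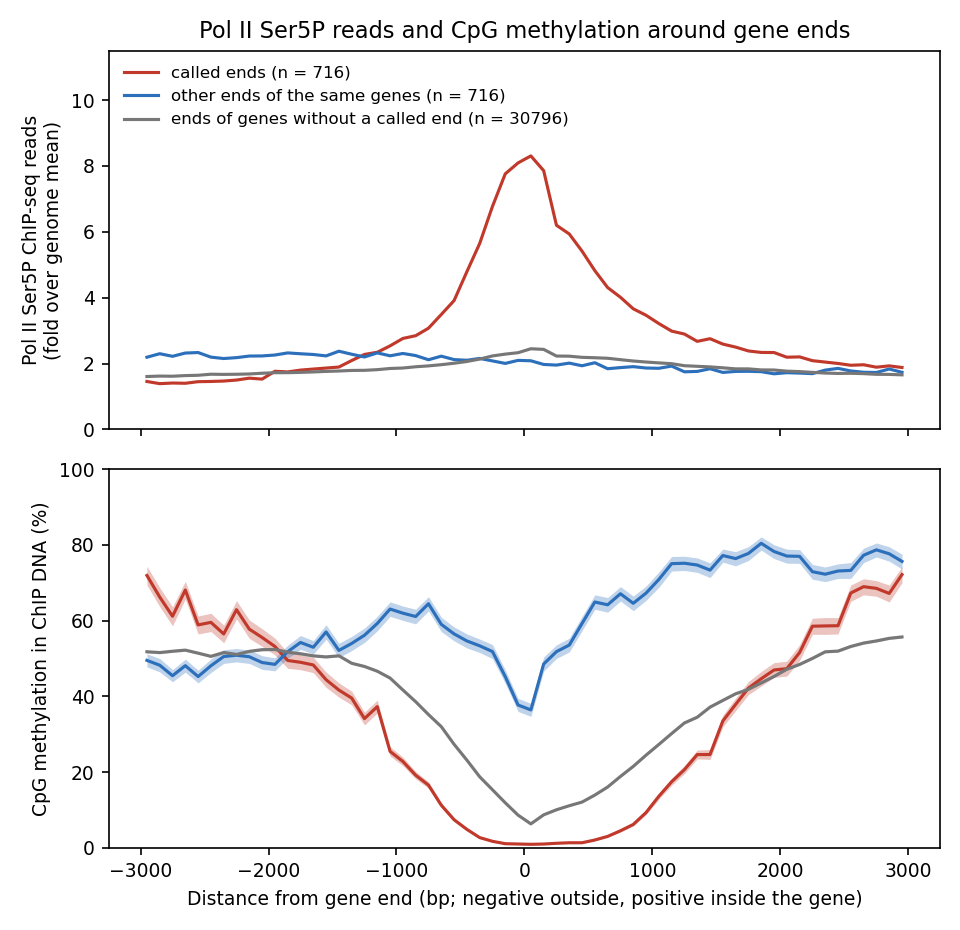
ChIP-seq reads as fold over the genome mean (upper panel) and CpG methylation in percent with its 95% interval (lower panel), in 100 bp bins by distance in bp from a gene end, negative outside the gene. Called ends (716) reach 8.31-fold and fall to 0.928% methylation, while the other ends of the same genes stay at or above 36.4%.

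Against their own flanks, 12916 of 18590 tested ends were lower by Fisher's exact test, 1897 were higher and 3777 did not pass. Among 843 called ends, 810 were lower and 16 higher, with a median difference of -60.3 percentage points. Among the 17747 others, 12106 were lower and 1881 higher. The smallest p-values among decreases, which also depend on the number of calls, were at Impdh2, an enzyme of guanine nucleotide synthesis (1.03% of 1072 calls), Dapk3 (0.786%), Mogs (0.836%), and Yipf3 and Polr1c (1.01% and 1.03%), whose ends are 35 bp apart. None of these 5 ends was called. Flank methylation at these ends lay between 78.4% and 85.8%. The smallest p-values among increases were at Sco2 (89.8% against 20.9% in the flanks), Rabepk (85.7% against 6.63%), Fam166a (80.8% against 5.25%), and at Rpl7a and Surf1 (69.5% against 7.09% and 68.6% against 7.23%), whose ends are 66 bp apart. None of these was called either. The test compares reads within 1 library. The count of higher ends was 538 of 11775 tested with at least 50 calls on each side and 2823 of 25112 with at least 10.

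Pooled methylation fell as reads rose. Ends were put into 5 equal groups by ChIP-seq reads, and 3.63% of ends were measured in the group with the fewest and 94.0% in the group with the most. Methylation was 26.6% in the former and 3.74% in the latter. The mean over ends did not fall at every step, at 36.7%, 32.1%, 33.2%, 26.8% and 14.7%. Across ends, which are not independent replicates, Spearman's rho was -0.23 between reads and methylation, -0.43 between fold over background and methylation, and -0.70 between CpG density and methylation. Within the low, middle and high CpG classes, rho between reads and methylation was -0.18, -0.22 and -0.02. Called ends were lower than the others in each class, with 20.7% against 55.1% in the low, 1.18% against 3.66% in the middle and 0.856% against 1.03% in the high class. The low class held 39 measured called ends. In the high class both values lie below the 1.64% of methylated calls in mitochondrial DNA, used below to bound incomplete conversion. That difference can therefore not be read as one of methylation.

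**Figure D2:**
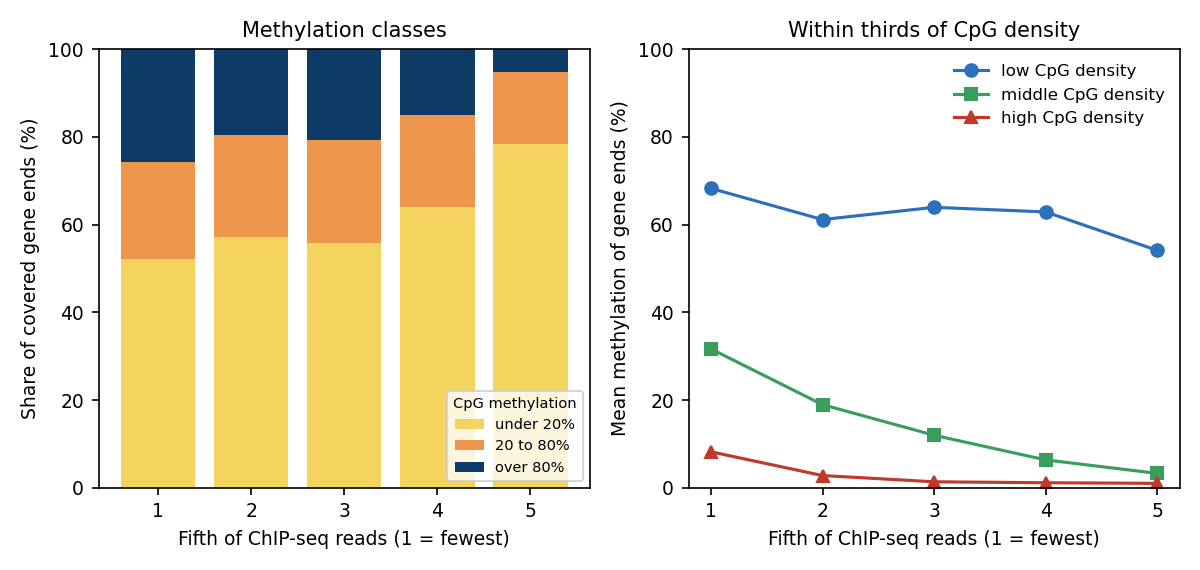
Share in percent of measured gene ends in each methylation class (left) and mean methylation in percent by CpG density class (right), across 5 equal groups of ends by ChIP-seq reads, 1 having the fewest. Mean methylation in the middle CpG class goes from 31.7% to 3.28%, and in the high class from 8.22% to 1.02%.

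Regions were sought in the whole genome, whether or not a gene end was near. Of 892 regions, 567 lay within 1 kb of an annotated gene end, 145 within genes and 180 between genes. Median methylation was 0.847%, 2.5% and 5.26%, and 99.1%, 90.4% and 84.4% of the measured regions were under 20%. The share of all calls that were methylated gave another order of size, at 1.52%, 38.1% and 77.4%. A few regions with very many calls set those values. Without the 28 regions holding over 1000 calls, a setting chosen after seeing the data, they were 1.06%, 4.28% and 13.2%. The 5 regions away from gene ends with the most reads lay between genes and were highly methylated. On chromosome 9 from 3000001 to 3001000, 78.1% of 7488 calls on 46 cytosines were methylated. On chromosome 2, the values were 85.9% of 79801 calls on 32 cytosines from 98666501 to 98667000 and 74.9% of 12071 calls from 98662501 to 98663000. On chromosome 15 from 75086001 to 75087000 it was 79.7% of 910 calls, and on chromosome 14 from 19417501 to 19418000 it was 80.2% of 3588 calls. In all 5 regions the calls per cytosine were far above the autosomal mean of 1.8. No input library was used, so an excess of reads that does not depend on the antibody cannot be ruled out. These regions can therefore not be taken as Pol II Ser5P binding sites.

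Gene lists of cortical cell types and of genes silent in cortex were compared next. Genes used by neurons and by all cells had more reads than matched random lists, while their methylation was not set apart from lists matched on CpG class and reads. Median methylation was 1.20% for housekeeping (percentile 83.7), 1.74% for synaptic and neuronal (percentile 56.4) and 0.841% for immediate early genes (percentile 30.9). In the housekeeping list 16 of 18 genes were called at 2-fold and 3 at 4-fold, with a median of 261.5 reads (percentile 100 among matched random lists) and 1.88% methylation (1.24% in the strongest window of each gene). Besides Polr2a, the elongation factor gene Eef1a1 had 0.707% of 1131 calls and Ppia 1.63%, while the ends of Actb and Ldha with more reads had 28.3% and 90.5%. In the synaptic and neuronal list 13 of 22 were called at 2-fold, with a median of 158 reads (percentile 100) and 6.72% methylation (3.54% in the strongest window of each gene). Tubb3, a neuronal tubulin gene, had 0.892% of 785 calls, the neurofilament gene Nefl 1.18% and the synapsin gene Syn1 0.599%, with Nefl and Syn1 called at 4-fold and Grin1 at 8.07%. Rbfox3, Cplx2, Camk2b and Syp had between 60.3% and 86.9% at the end with more reads. In the strongest window of each gene, Rbfox3 had 0.939% of 213 calls and Syp 1.85% of 54 calls. Cplx2 had 28.4% of 81 calls there and Camk2b 87.2% of 78 calls. Of 16 immediate early genes, which neuronal activity induces, 11 were called at 2-fold and 4 at 4-fold, with a median of 157.5 reads and 1.30% methylation. Arc and Btg2 were called at 4-fold, with 0.796% and 0.827%. Egr1 had 0.725% and Dusp1 0.881%. Npas4 and Nr4a1 had 20.4% and 48.6%, but 1.73% and 1.39% in the strongest window of each gene.

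A whole cortex also holds glial and vascular cells. The median reads were at percentile 95.9 for astrocyte, 99.9 for oligodendrocyte, 89.9 for microglial and 34.5 for endothelial and blood genes. None of these 4 lists had an end called at 4-fold. At 2-fold, 6 of 10 astrocyte, 3 of 10 oligodendrocyte, 4 of 10 microglial and 1 of 10 endothelial and blood genes were called. Pooled methylation was 5.04%, 11.6%, 19.3% and 4.45% over 9, 8, 7 and 3 measured genes. Median methylation was at percentiles 74.7, 53.6, 71.0 and 32.1 among lists matched on CpG class and reads. The methylation of these lists was therefore not set apart either. The last 2 pooled values depend on the setting, with 7.38% for microglial genes in the strongest window of each gene. For endothelial and blood genes the pooled value was 9.74% with at least 10 calls and 13.8% within 500 bp. Among astrocyte genes, Glul, Sox9 and Slc1a3 had 0.722%, 1.26% and 3.70% and Gfap 17.5%, with Aldoc and Slc1a2 at 41.4% and 82.6%. At their opposite ends Aldoc and Slc1a2 had 1.41% of 71 calls and 0.592% of 169 calls. Among oligodendrocyte genes, Olig1, Olig2 and Cnp had 1.08%, 2.99% and 1.03%, and the myelin genes Mbp and Mag 40.5% and 27.3%, with Sox10 at 59.4%. The opposite ends of Mbp and Sox10 had 0.735% of 136 calls and 5.94% of 101 calls. Among microglial genes, C1qa had 17.1%, Cx3cr1 13.5%, P2ry12 32.5% and Csf1r 67.6%. The endothelial genes Flt1, Kdr and Cldn5 had 1.23%, 16.1% and 0 of 29 calls (upper bound 11.9%).

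Germline and receptor genes carried few reads. The germline list had a median of 24 reads (percentile 0.465). Over 6 measured genes its pooled methylation was 28.2% and its median 83.4% (percentile 99.97), since Zpbp2 gave most of the calls. With the strongest window of each gene in place of an end, the pooled value was 16.3% and the median 6.67% over 5 genes, so this list does not keep its high median. Dazl, Sycp3 and Slc25a31 had 91.9%, 80.4% and 59.0%, whereas Zpbp2 had 0.316% of 316 calls and was the member called at 2-fold. Of 1465 olfactory and vomeronasal receptor genes, 2 were called at 2-fold, the median was 14 reads, and 9 were measured, with a pooled value of 31.6% (53.7% with at least 10 calls) and a median of 79.2%. Olfr283, Olfr157 and Vmn1r1 had 84.0%, 83.3% and 95.5% and Vmn2r29 24.0%. Vmn1r4, called at 4-fold with 0.881%, has an end of Nt5c3 94 bp away. In the liver and other-tissue list, with a median of 31.5 reads (percentile 15.8), 1 of 18 genes was called at 2-fold and pooled methylation was 8.55% (1.66% in the strongest window of each gene, 15.2% with at least 10 calls), with Acta1, Ckm, Apoa1 and Sftpc at 0.709%, 5.08%, 3.57% and 12.8% and Myh1 at 85.7%. Developmental regulators had a median of 63 reads (percentile 82.8) and 4.94% methylation, with 7 of 58 called at 2-fold and 1 at 4-fold. Hoxa5, Hoxa6, Gata6 and Nkx2-5 had 1.03%, 1.71%, 0.529% and 2.75%, and Lhx3, Hoxb6 and Hoxd13 had 70.2%, 20.6% and 34.8%. Of 85 histone genes, with a median of 65 reads (percentile 13.7), 34 were called at 2-fold and 13 at 4-fold, and pooled methylation was 1.24%. H2ax, H2az1 and H2aw had 0.877%, 0.861% and 0.412%, and H3c14 and H2ac1 37.1% and 92.0%. Imprinted genes had 9.09% over 17 measured genes, and their median of 7.55% was at percentile 99.97. Mcts2 had 18.2% of 446 calls, Meg3 3.28%, Zrsr1 2.85% and Igf2r 1.15%, while Gnasas1, Nnat, Airn and Gnas had 30.6%, 68.0%, 28.0% and 85.0%. The end with more reads need not be the start of a gene.

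**Figure D3:**
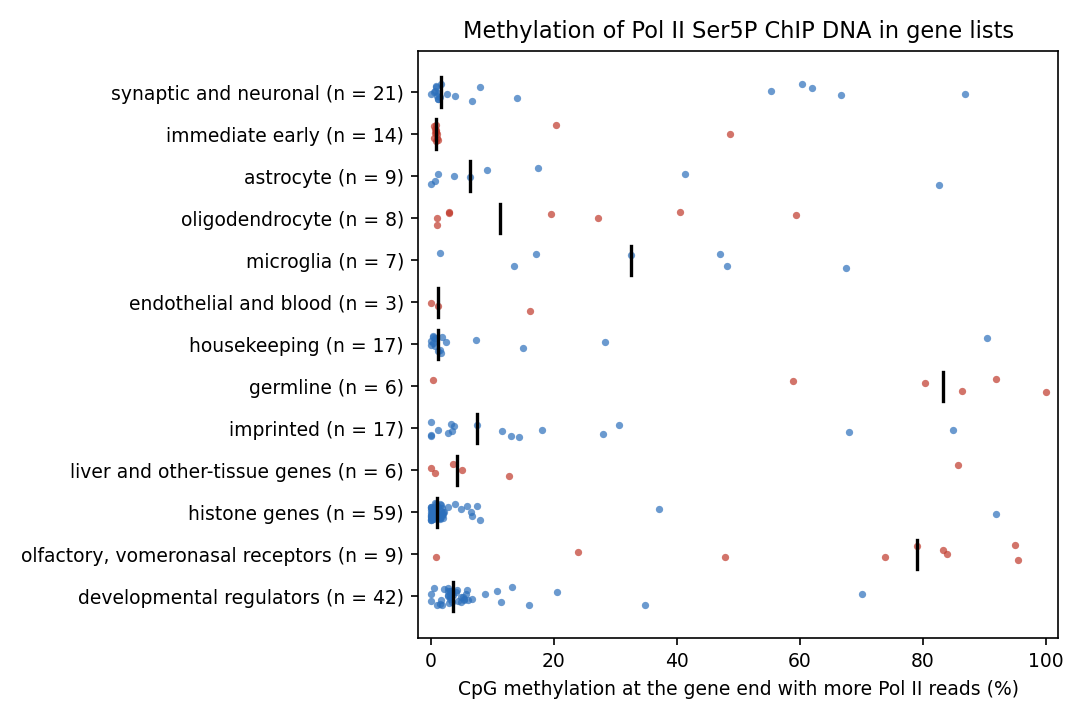
CpG methylation in percent at the gene end with more ChIP-seq reads for each measured member (points) of 13 gene lists, with the list median (black line) and the number of measured members (n). Medians are 83.4% for germline genes and 79.2% for olfactory and vomeronasal receptors, against 0.841% for immediate early and 1.20% for housekeeping genes.

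The X chromosome had 0.367 of the autosomal read density in ChIP-seq and 0.396 in the bisulfite library, in male animals with a single X. Of its ends 1.29% were called (0.839 to 1.90%), against 2.00% of autosomal ends (1.87 to 2.14%). With the mean of the own chromosome in place of the genome mean, 3.47% of X ends and 1.98% of autosomal ends were called at 4-fold. At 2-fold these shares were 17.7% and 19.3%. Methylation at called ends was 0.987% on X (0.745 to 1.28%) over 24 ends and 1.23% (1.19 to 1.27%) on autosomes.

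Both libraries ranked the ends alike, with Spearman's rho of 0.94 across ends. The bisulfite reads called 478 ends, of which 355 were among the 853 called by ChIP-seq, where independent calls would share 9.42. Relative to ChIP-seq, the bisulfite library had a median of 0.836 times the reads at called ends and 0.968 times at the others, after scaling to the same depth. Incomplete conversion was bounded by mitochondrial DNA, where 1.64% of 30402 calls were methylated (1.5 to 1.79%), so values near 1% lie within the range that unconverted cytosines can give.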

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

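Values outside the main comparisons were read from the mitochondrial genome and chromosome Y. Methylated calls made up 1.64% of 30402 calls on the mitochondrial genome and 67.8% of 37977 calls on chromosome Y (67.3 to 68.3%). The value was 58.4% on autosomes and 62.1% on X. Over cytosines with at least 5 calls, chromosome Y had 50.4%, autosomes 22.8% and X 15.5%, so the order of X and autosomes depends on depth. The mitochondrial genome and chromosome Y are listed because the comparisons of gene ends leave them out. No explanation was tested for either.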

How the results depend on the processing

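Settings at 2-fold, against the genome mean alone, with the own chromosome mean in place of the genome mean, with fixed CpG cuts, with the strongest window per gene and without regions of over 1000 calls were chosen after seeing the data. No paired analysis was possible because there was 1 library per assay, and no library could be left out. The most upstream start site and classes of CpG observed to expected ratio were not run, for want of transcripts and sequence. Called ends stayed less methylated than the others in every setting where both were measured, which leaves out calls within 250 or 1000 bp, with all reads kept, against the genome mean alone and with the own chromosome mean. Over all results, 90 alternatives moved a value beyond its counting interval or a count by over 1.5 times, and 48 did not. The intervals are narrow, since they rest on many calls, and the cause of a move was not tested unless named.

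The count of called ends (853) was 1760 within 250 bp, 201 within 1000 bp, 17 at 8-fold, 478 from bisulfite reads, 8244 at 2-fold and 7385 against the genome mean alone. X ends called went from 1.29% to 3.47% with the mean of their own chromosome.

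Methylation of called and other ends (1.22% and 6.42%) was 1.17% and 3.15% with at least 50 calls, 1.03% and 3.16% within 100 bp, and 1.6% and 10.2% within 500 bp. It was 0.932% and 5.90% at 8-fold, 1.29% and 6.2% with bisulfite reads defining calls, 1.04% and 6.92% without ends near another gene's end, and 2.27% and 13.0% at 2-fold. Other ends had 8.33% with at least 10 calls and 3.66% as a mean of cytosines. The share of called ends under 20% (97.4%) was 98.4% with at least 50 calls, 98.7% within 100 bp, 100% at 8-fold and 89.6% at 2-fold. For other ends (67.0%) it was 51.4% with at least 10 calls, 89.8% with at least 50, 88.3% within 100 bp, 50.1% within 500 bp and 84.7% as a mean of cytosines. It was 68.3% at 8-fold, 63.5% with classes at 10% and 90%, 65.4% without ends near another gene's end and 52.9% at 2-fold. Ends with few calls are mostly CpG-poor, so the depth of calls limits this share.

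Ends higher than their flanks (1897) numbered 538 with at least 50 calls and 506 within 100 bp. In groups by fold over background, methylation was 25.1% in the lowest and 2.38% in the highest (26.6% and 3.74% by reads). With CpG cuts of 2 and 5 per 100 bp, other ends had 61.3%, 13.4% and 1.16% and called ends 42.5%, 2.05% and 0.934% in the low, middle and high classes. Both values of the high class lie below the 1.64% of mitochondrial calls.

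Regions near gene ends, within genes and between genes (567, 145 and 180) numbered 5, 3 and 4 at 8-fold and 8909, 5439 and 2807 at 2-fold, and those within genes 92 with a 5 kb limit. Their methylation (1.52%, 38.1% and 77.4%) was 0.813%, 80.1% and 85.5% at 8-fold, 1.44%, 31.3% and 80.1% with all reads kept, 6.11%, 25.5% and 79.0% with a 5 kb limit, 2.17%, 8.89% and 64.0% at 2-fold, and 1.06%, 4.28% and 13.2% without regions of over 1000 calls.

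Pooled methylation of gene lists moved by over 1.5 times in some settings. With the strongest window per gene it went from 28.2% to 16.3% in germline, 19.3% to 7.38% in microglial, 8.55% to 1.66% in liver and other-tissue, 6.72% to 3.54% in synaptic and 1.88% to 1.24% in housekeeping genes. Within 500 bp it was 46.4% in germline and 13.8% in endothelial and blood genes (4.45%). With at least 10 calls it was 9.74% in endothelial and blood, 15.2% in liver and other-tissue and 53.7% in receptor genes (31.6%).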

Other observations

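Noncoding genes were counted without ends within 1 kb of a coding gene end, so their shares cannot be set against those of coding genes, where no ends were left out. On this basis, 17 of 974 small nuclear RNA genes were called at 4-fold and 28 at 2-fold (2.87%, 1.92 to 4.13%), where Rnu1a1, Gm22068 and Gm22513 had the most reads. Rnu1a1, Rnu11, Rnu2-10 and Rnu3b1 have products that belong to spliceosomal and nucleolar particles. The 2-fold called ends of small nuclear RNA genes had 1.13% methylation, against 9.71% and a median of 56.5% over all measured ends of these genes. Transfer RNA genes, which another polymerase transcribes, were called at 2-fold in 46 of 360 cases (12.8%, 9.51 to 16.7%). Long noncoding RNA genes were called at 2-fold in 5.35% of 12478, with Malat1 and Mir124a-1hg near the top, and pseudogenes in 0.49% of 9788. The genes in this paragraph were chosen after their values were seen.

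The tests below on background at methylated called ends, on body read density at matched gene length and on imprinted genes were chosen after the results were seen. The count over distinct windows for background was added when its value for ChIP-seq folds was already known, and the values outside the chosen stretch were added after those of the whole peak window were seen. Prss12, Cct6a and Septin5 were named after their values were seen. The others were written before their values were computed. For the imprinted genes, the explanation that concerns both alleles was also reworded after its value was known, from any window to windows that are 50% methylated, because equal binding to both alleles of an unmethylated window gives low values too. A comparison with matched gene ends and a model of background from both alleles were also tried there after the values were seen. They are not reported, because the former measured ends in place of windows and the bounds of the latter were set with its value in view.

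The 22 called ends with 20% methylation or more lie mostly in short genes, with a median length of 3.97 kb against 28.9 kb for genes with other called ends, though Prss12 and Cct6a span 59.7 and 59.1 kb, and 21 of them are in the low CpG class, which holds 39 measured called ends. Unbound background DNA as the whole source stays open. The lower bound of methylation exceeded the share of reads that background would give at 17 of the 22 ends. By distinct windows this held in 14 of 19 (13 with folds from the bisulfite reads). Ends chosen at 20% and at 4-fold, where that share is at most 25%, favour this outcome. The share also comes from reads within 500 bp and methylation from calls within 250 bp, so the share in the measured window is not known. An unmethylated Pol II peak beside the measured window and within 500 bp is argued against for most of the 22 ends. Median methylation was 52% around the densest point within 500 bp. It was 61.0% over 17 distinct windows outside the stretch the ends were chosen by, with a lower bound over 20% in 13. Such a peak stays open for the rest, with values under 20% at Cct6a (1.46% of 137 calls), Septin5 (9.72% of 576) and Septin3 (17.6% of 34). The densest point lay as far as 500 bp away, the limit of the search, so a peak farther out stays open for all 22. Flank methylation 1 to 3 kb away ranged from 2.10% to 82.8%. Pol II along the whole gene remains a candidate explanation: body read density had a median of 6.88-fold over the genome mean in 20 genes, above all 10000 random lists matched on gene length (percentile 100, highest 4.92-fold), while percentile 97.7 among single genes of other lengths decides nothing. Low CpG density, windows shared with a neighbouring gene and ends that are where a gene stops stay open, and no biological explanation was tested.

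In the 500 bp window with the most reads of each imprinted gene, pooled methylation was low, at 7.85% of 4945 calls (7.11 to 8.63%) over 20 measured genes. Windows that are 50% methylated with both alleles immunoprecipitated alike would give at least 40%, and the upper bound of 8.63% lies under this. That wording was set with the value known. The windows were chosen by reads, and whether they cover a region methylated on a single allele was not examined. Equal binding to both alleles at such regions was therefore not tested. Windows that are unmethylated on both alleles cannot be told apart from binding to the unmethylated allele, with a median window at 6.53%, because methylation of cortex DNA that was not immunoprecipitated was not analysed here. Nnat was the highest, at 34.0% of 53 calls, and the 1 window of 20 not under 20%, followed by Mest (18.0%) and Mcts2 (17.9%), with Peg3 (0.833%) and Igf2r (0.968%) among the lowest. Nnat, Mest and Peg3 were chosen after their values were seen.

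Lower methylation at ends with more reads was set against CpG content and depth of calls. The gap in mean methylation between the groups with the fewest and most reads was 14.2, 28.4 and 7.2 percentage points in the low, middle and high CpG classes, so CpG density in these classes does not account for the whole gap. The groups with the fewest reads held 87, 158 and 69 ends, and in the high class 7 of the 69 ends carried the gap, with medians of 1.09% and 0.807% and a rho of -0.02. With 20 calls drawn per end the gap was 22.1 points, which decides nothing, since drawing calls leaves the expected percent of each end unchanged. Call depth, the absence of ends with too few calls and CpG density within a class stay open, and no biological explanation was tested.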
